A study of Mus musculus with 516 samples.

How the data were processed

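Single cells of mouse dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, were profiled by RNA sequencing in 516 samples of 1 cell each. Per the labels, the cells came from 2 inbred strains, C57BL/6 and CAST/Ei, and were taken either right after dissociation (naive) or after in vitro axotomy, in which the dissociated cells were plated for 48 h, given the mitotic inhibitor ara-C at 24 h, and lifted again (labelled injured, called cultured here). There were 132 naive and 111 cultured C57BL/6 cells, and 174 naive and 99 cultured CAST/Ei cells. Neuron-like cells, as classed below, numbered 116 and 36 in C57BL/6 and 156 and 75 in CAST/Ei. Dissociated cells were purified over Percoll of density 1.04, passed through a mesh of 35 µm and captured on a microfluidic chip, up to 192 cells per run, per the labels' protocols. Lysis, reverse transcription from the polyA tail and amplification took place on the chip, and tagmented libraries were sequenced on an Illumina NextSeq instrument, per the labels' protocols. The libraries carry no molecular identifiers, so amplified copies of a molecule count as separate reads.

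The authors deposited 1 table of raw read counts, whole numbers per gene and cell, with 11251 genes and 516 columns, each of which was matched to its sample by title. No column of the table was left unused. Bowtie2, SAMtools and the mouse genome build mm10 are named, without versions or roles, per the submitters' processing notes. The counting program, the gene annotation and any filter on genes or cells are not given in the sources used here. Every gene of the table has a read in at least 60 of the 516 cells, and no gene carries a mitochondrial name, so genes of few cells and mitochondrial transcripts were not analysed here. Some fixed gene lists have fewer members in the table than were listed, most of all the macrophage list with 1 of 11 genes, the other immune markers with 0 of 6 and the erythroid markers with 0 of 7, while the heat shock, cell cycle, oxidative phosphorylation and matrix lists are complete. Of the regeneration-associated list 26 of 30 genes are in the table and of the neuron subtype list 36 of 40. Bowtie2 does not join reads across introns by design, and reads of CAST/Ei cells carry that strain's sequence variants against the C57BL/6 reference, and both can lower the count of a gene.

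Labels name no animal, culture or capture run. Each of the 4 groups was therefore treated as 1 sample, nothing was tested between groups, and no p-value, standard error or number of differing genes was derived from cells. Comparisons give both values with exact 95% Poisson intervals for sums of reads and exact (Clopper-Pearson) 95% intervals for shares of cells, which cover counting error only, as do the limits given for a count of 0, taken as 3 counts. The design of each comparison, the gene lists and most alternatives were fixed before the data were examined.

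All cells were clustered together without a filter. Reads were scaled to each cell's total as CPM and taken on the log2(CPM + 1) scale. Then 2000 variable genes were reduced to 20 principal components, and a graph of 15 nearest neighbours was divided by the Leiden method at resolution 1, which gave 13 clusters. A cluster was named from the fixed marker list with the highest mean, among lists with at least 3 genes in the table. The name was dropped where the cluster's leading 10 genes by fold held more markers of another class than of that one. Clusters 2 and 6 were so named without a marker of their class among those genes. Clusters 1, 3, 8, 9, 10, 11, 12 and 13 (naive cells, with 1 cultured cell each in clusters 3 and 11) and clusters 2 and 5 (cultured cells) were called neuron-like, and cluster 6 was called glia-like, with Sfrp1, Crabp1 and genes of cell division such as Nusap1 and Cenpa in the lead. Cluster 4, in which the fibroblast list was highest (mean 8.90, against 4.39 for the neuron list) and Spp1, Trf and Fn1 led, stayed unnamed. Its leading genes held 0 fibroblast markers and 1 of another class, Spp1, a neuron subtype marker that counted as neuron. Cluster 7, in which the neuron list was highest while endothelial and interferon-induced genes such as Flt1, Tgtp2 and Iigp1 led, stayed unnamed as well. Because naive and cultured neuron-like cells fall in different clusters, apart from those 2 cells, and clusters 3, 8, 9, 10, 11 and 13 hold naive cells of 1 strain, values were compared over the whole class. No doublet caller was run, and doublets were weighed by leaving out the neuron-like cells with the highest glial expression, as an alternative that left 98 naive and 14 cultured C57BL/6 cells and 134 naive and 41 cultured CAST/Ei cells.

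Reads were summed over the neuron-like cells of a group and expressed as CPM, and groups were compared by the log2 ratio of CPM + 1. Folds given as at least a value set a sum without reads at 3 reads instead, and cannot be set beside those ratios. Genes named one by one had at least 20 CPM in either group, at least 5 reads in 30% of its cells, a log2 ratio and a difference of the cells' mean log2(CPM + 1) of at least 1 in the same direction, and ranked among the first 12 higher or 12 lower by that difference. For the difference of the culture response between strains the 5 genes with the largest differences each way were named, and members of the fixed lists were named from those with large or small ratios, some of them for their known roles and after their values were seen. A few genes that these rules select are not reported here. For each of 17 gene lists the median log2 ratio of the members with at least 5 CPM in either group was set against 10000 random lists of equal size matched on mean expression in 10 bins. A list is called apart where its percentile was under 2.5 or as close to 100, as a description of these cells. The lists were regeneration-associated genes, neuron subtype markers, ion channels and opioid receptors, pan-neuronal genes, immediate early genes, heat shock, cholesterol synthesis, activin and BMP signalling, cell cycle, nuclear oxidative phosphorylation, interferon and antigen presentation, extracellular matrix and adhesion, sex-linked genes, glial injury, and markers of glia, of macrophages and of fibroblasts and vessels.

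Shares of cells with a marker were taken after each cell was thinned at random to 230000 reads, with a gene detected at 5 or more reads. Cells shallower than that were left out, 50 in all, which removed 8 of 116 naive and 8 of 36 cultured neuron-like C57BL/6 cells, and 11 of 156 naive and 11 of 75 cultured neuron-like CAST/Ei cells. Alternatives changed the clustering method, the weighting of cells, the scaling, the pseudocount, the filters on list members and on cells, and the range of cell numbers in the titles. A further 3 were chosen after seeing the data, namely C57BL/6 cultured cells without reads of Ddx3y and cultured cells of cluster 2 or of cluster 5 alone.

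The steps were tested on simulated counts for the 11251 genes with 200 genes moved by known amounts. With the cell numbers of the C57BL/6 culture comparison (36 and 116 cells), genes moved by 3 on the log2 scale came back at a median of 2.92 and 33 of 33 passed the rule for named genes, genes moved by 1 came back at 0.89 and 5 of 33 passed, and 35 of 11026 unmoved genes passed. In the simulated comparison of cultured cells between strains (75 and 36 cells) 118 of 11026 unmoved genes passed, against 1 for culture in CAST/Ei and 0 for the naive strains. Simulated lists of 25 genes moved by 1 stood at percentile 100 in all 4 comparisons, with medians between 0.82 and 1.09, and unmoved lists lay between percentiles 12.2 and 81.0. Genes were drawn independently of each other from the mean and spread of 1 group. Cell subtypes, animals, cultures, capture runs and RNA of other cells were not simulated, so these rates are not the error rates of the real comparisons.

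Gene positions come from the GENCODE vM21 annotation of GRCm38, the assembly also called mm10, whose gene models may differ from those the authors counted. Of the 11251 genes, 11185 matched it by symbol. Genes with at least 10% of their 31-base words in another annotated gene, here among others Serpina3h, Serpina3g, Gm15446, Zfp780b, Mx2, Hopx, Sap18, Zfp367, Mir703, Pisd-ps1, Gm14403, Fam60a, Rpl21, Spp1, Ube2c, Cd55, Lhfpl1, Sirt5 and Xist, are uncertain because reads may be divided between copies, as are the Mrgpra and Mrgprb receptors, H2-T24 and the Hspa1a and Hspa1b pair. Overlapping and antisense genes are uncertain too, since the use of strand in counting is not given in the sources used here. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.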

Results

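The table holds 496696577 reads over 11251 genes in 516 single cells, with 13932 to 2978345 reads per cell and a median of 839147. They came from 2 inbred mouse strains, C57BL/6 and CAST/Ei, and were captured either freshly dissociated (naive) or after 48 h in culture as a model of axotomy. Naive C57BL/6 cells had a median of 696013 reads and 8401 genes with a read, and cultured ones 729522 reads and 7999 genes. Naive CAST/Ei cells had 960205 reads and 8548 genes, and the 99 cultured ones 1111710 reads and 7212 genes. CAST/Ei cells were thus sequenced more deeply, while cultured CAST/Ei cells had the fewest genes. No replicates of a group are labelled, so no difference below has a replicate check.

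The first question was which kinds of cells each preparation held. Neuron-like cells made up most of both naive preparations, 87.9% in C57BL/6 (95% interval 81.1 to 92.9) and 89.7% in CAST/Ei (84.1 to 93.8). After culture the share was 32.4% in C57BL/6 (36 cells, 23.9 to 42) and 75 of 99 in CAST/Ei (75.8%, 66.1 to 83.8). Glia-like cells, cluster 6, in which the satellite and Schwann list had the highest mean of the marker lists, were 28.8% of cultured C57BL/6 cells (32 cells, 20.6 to 38.2) and 11.1% of cultured CAST/Ei cells (11 cells, 5.68 to 19). No naive cell lay in cluster 6, which by counting alone allows shares there of up to 2.27% in C57BL/6 and 1.72% in CAST/Ei. Naive and cultured cells hardly shared any cluster, so this sets no limit on glia in the naive preparations. The unnamed cluster 4, with high fibroblast markers, held 38.7% of cultured C57BL/6 cells (43 cells, 29.6 to 48.5), 13.1% of cultured CAST/Ei cells (13 cells, 7.18 to 21.4) and no naive cell. Cluster 7, with endothelial and interferon-induced genes in the lead, held 12.1% of naive C57BL/6 cells (16 cells, 7.09 to 18.9) and 10.3% of naive CAST/Ei cells (18 cells, 6.25 to 15.9). Its mean log2(CPM + 1) was 6.74 for the neuron list, 6.06 for the satellite and Schwann list and 4.42 for the endothelial list. Cluster 7 held no cultured cell, which allows up to 2.70% and 3.03%. With Ward clusters the cultured CAST/Ei share of neuron-like cells was 61.6%, and with each cell classed by its own marker means it was 62.6%. Shares of captured cells can be set by the density step, the mesh and the chip as well as by the culture.

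**Figure D1:**
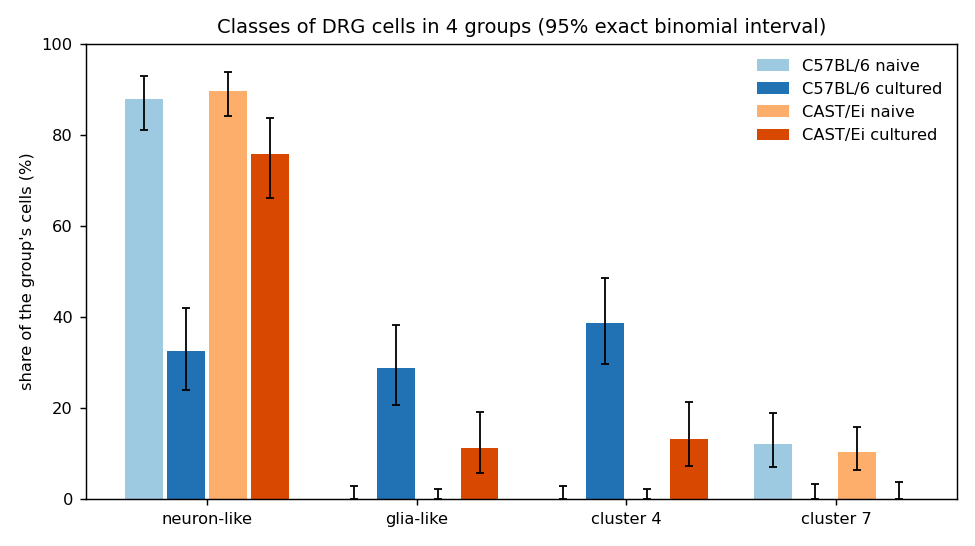
Bars show the share of each group's cells (vertical axis, percent) that were neuron-like, glia-like, in cluster 4 or in cluster 7, with exact 95% binomial intervals, for naive and cultured cells of C57BL/6 (blue) and CAST/Ei (orange). Neuron-like cells were 32.4% of cultured C57BL/6 and 75.8% of cultured CAST/Ei cells, against 87.9% and 89.7% before culture.

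How neuron-like cells differed after axotomy and 48 h in culture was asked first in C57BL/6. Here 36 cultured neuron-like cells (12 of cluster 2, 23 of cluster 5 and 1 of cluster 11) with 20281173 reads were compared with the naive ones of clusters 1, 9, 11, 12 and 13, with 94601442 reads. Genes known to be induced in injured sensory neurons were higher in the cultured cells, and genes of neuron subtypes, ion channels and synapses were lower. Naive and cultured cells are different cells. In both strains, a change within neurons cannot be told apart from a change in which neurons were captured. Sprr1a, a small proline-rich protein of regrowing axons (chromosome 3, 92483952 to 92485895), had 544 CPM (534 to 554) in cultured against 0.148 CPM (0.0809 to 0.248) in naive cells. The injury transcription factors Atf3 (738 against 191 CPM), Jun (621 against 144.8) and Sox11 (2888 against 234) were higher as well. Of the 26 regeneration-associated genes measured, 21 were at least 2-fold higher and 2 at least 2-fold lower, with a median log2 ratio of 2.03, above all matched random lists (percentile 100). Tnfrsf12a, the TWEAK receptor, stood at a log2 ratio of 3.83, the tubulin Tubb6 at 3.69 and the growth cone protein Gap43 at 1.74. Npy, a neuropeptide, had no read in naive cells and 16.8 CPM in cultured cells, at least 529-fold higher. This bound takes the naive sum as 3 reads, so it is not on the scale of the log2 ratios of CPM + 1, that of Npy in CAST/Ei included. It was detected in 25% of cluster 2 and 4.35% of cluster 5 cells, and glia-like cluster 6 of the same culture had 13.2 CPM. The cytokine Il6 (-1.83) and the leukaemia inhibitory factor receptor Lifr (-1.25) were the 2 members lower by at least 2-fold.

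Among neuron subtype markers in C57BL/6, 24 of 36 were at least 2-fold lower and 4 higher in cultured cells (median log2 ratio -2.71, percentile 0, or -2.68 with genes of no reads at the limit of 3 reads). Th, the enzyme of dopamine synthesis that marks low-threshold C fibres, had 1.48 against 724 CPM. Mrgprd, a receptor gene of itch and pain fibres, had 3.35 against 121.9 CPM, and the neuropeptide gene Tac1, which encodes substance P, 35.6 against 1095. Calcb, which encodes a calcitonin gene-related peptide, had 52.4 CPM (49.3 to 55.7) against 1142 (1135 to 1149). Spp1, which encodes osteopontin (5.30), Nts, which encodes neurotensin (4.29), and Adcyap1, which encodes PACAP (2.29), were on the subtype list but higher. Spp1 also leads the genes of the unnamed cluster 4 of cultured cells, so RNA of other cultured cells cannot be told apart as its source. Ion channels and opioid receptors followed with 16 of 23 at least 2-fold lower and 2 higher (median -2.32, percentile 0). Examples are the sodium channels Scn10a (33.9 against 366 CPM) and Scn11a (18.3 against 350.2), and the opioid receptor Oprm1 (0.394 against 19.1). Kcna1 (1.17) was among the higher ones. Pan-neuronal genes were lower by less (median -0.89, percentile 0.055, 8 of 23 at least 2-fold lower and 3 higher), with the synaptic vesicle protein Syp at -2.80, Snap25 at -2.08 and Tubb3 at -0.22. Many of them, Snap25 and Tubb3 included, were also markers used to call clusters neuron-like, so this choice of cells may have limited their fall.

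Lists tied to the surroundings and to growth were higher in the cultured C57BL/6 cells. Extracellular matrix and adhesion genes had a median of 2.24 (17 of 22 at least 2-fold higher, 1 lower), with Tnc at 4.85, Timp1 at 4.62 and the intermediate filament Vim at 2959.6 against 198 CPM. Activin and BMP signalling genes had a median of 1.55 (percentile 99.96, 11 of 17 higher, 1 lower), led by the activin subunits Inhba (58.9 against 0.296 CPM) and Inhbb (109.6 against 2.03), with Fstl1 lower (2705 against 12962). All 13 cell cycle genes were at least 2-fold higher (median 4.22, percentile 100), with the DNA topoisomerase Top2a at 214 against 0.243 CPM and Cdk1 at 172.9 against 0.285. Markers of other cells were higher in the same cells. Satellite and Schwann glia genes had a median of 1.58 (9 of 15 higher, 2 lower), with Sox10 at 78.8 against 2.92 CPM. Glial injury genes had a median of 3.50 (7 of 9 higher), fibroblast and vascular genes 1.28 (6 of 11 higher, 2 lower), and Cd68, the macrophage gene measured, stood at 2.13. Interferon and antigen presentation genes (0.27, 3 of 10 higher and 3 lower) and nuclear oxidative phosphorylation genes (-0.38, 0 of 21 higher and 2 lower) were not apart from matched lists.

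The genes farthest apart by the naming rule in C57BL/6 included, besides Sprr1a, Top2a, Nts and Spp1, the guidance protein Sema6a (392 CPM, 383 to 401, against 6.81, 6.29 to 7.35), and the galectin Lgals3 (869 against 15.2). The matrix genes Fbln2, Col5a2 and Postn (3.98, 4.99 and 5.13) and the mitotic genes Ube2c, Cenpf and Prc1 (6.67, 6.62 and 5.71) also ranked here. On the lower side stood the potassium channel partner Dpp10 (3.55 CPM, 2.78 to 4.47, against 228, 225 to 231). With it were the mitochondrial creatine kinase Ckmt1 (-5.85), Paqr5 (-5.58) and the sensory neuron transcription factor Isl2 (-5.12). Also lower were the Ras activator Rasgrp1 (-4.62), the sterol transporter Abcg1 (-4.53), the glycolytic enzyme Aldoc (-4.03), Rab27b (-3.86), Susd2 (-3.74), Nap1l5 (-3.15) and Serpina3g (-1.54). Sprr1a, Nts, Sox11, Gal and Gpr151 are among the 10 leading genes of cluster 5, and Npy and Inhbb of cluster 2, so they also helped to set these cells apart. The subtype median was -1.50 with a pseudocount of 10 CPM and -3.84 with cultured cells of cluster 2 alone, where the fibroblast and vascular median was -0.65.

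**Figure D2:**
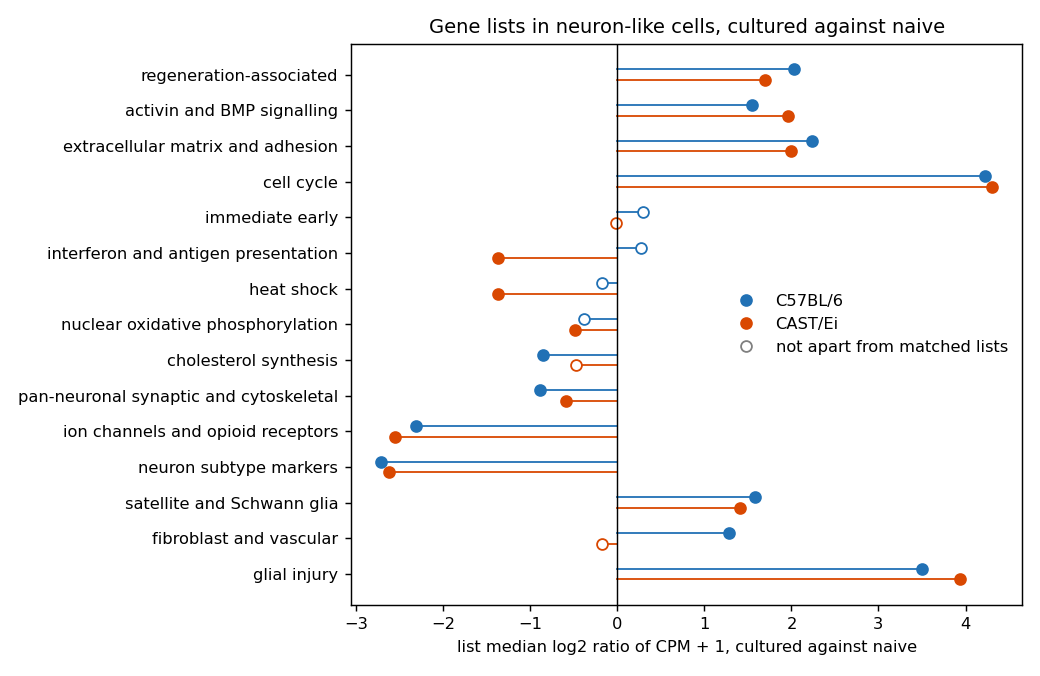
Each point is the median log2 ratio of CPM + 1, cultured against naive neuron-like cells (horizontal axis), of 1 gene list (vertical axis) in C57BL/6 (blue) or CAST/Ei (orange), filled where the list lay apart from matched random lists. Both strains show regeneration-associated genes higher (2.03 and 1.70) and neuron subtype markers lower (-2.71 and -2.63), while interferon and antigen presentation genes stood at 0.27 and -1.37.

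The same comparison in CAST/Ei, a wild-derived strain whose injured sensory neurons are known to regrow axons more readily, set 75 cultured neuron-like cells (44 of cluster 2, 30 of cluster 5 and 1 of cluster 3) against naive ones of clusters 1, 3, 8, 10 and 12. They hold 80707089 and 159154185 reads. Regeneration-associated genes were higher and subtype and channel genes lower here too. Sprr1a had 540.2 CPM (535 to 545) against 0.647 (0.528 to 0.785), and the neuropeptide gene Gal, which encodes galanin (chromosome 19, 3409915 to 3414544), had 3240.2 (3228 to 3253) against 199 (196 to 201). Of 26 regeneration-associated genes 20 were at least 2-fold higher and 0 lower (median 1.70, percentile 100). Examples were Npy at 6.53, Sox11 at 3.97, Smad1 at 2.41 and Atf3 at 0.95, and Lifr (-0.02) and Bdnf (-0.36) at the low end. Subtype markers had a median of -2.63 (percentile 0, 27 of 36 at least 2-fold lower, 2 higher). Tac1 had 34.8 against 977 CPM, Th 15.1 against 665 and the somatostatin gene Sst 1.99 against 86.7. Spp1 (6.02), which also leads cluster 4, and Adcyap1 (2.58) were higher. Ion channels and opioid receptors had a median of -2.56 (percentile 0, 13 of 22 lower, 2 higher). Scn11a had 19.8 CPM (18.8 to 20.8) against 427 (424 to 430.4), and Kcna1 was higher at 456 against 64.1. Pan-neuronal genes had a median of -0.59 (percentile 1.02, 7 of 23 lower, 2 higher), with Ina at -2.70 and Snap25 at -1.59. Their overlap with the markers that named neuron-like clusters applies here too.

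Activin and BMP signalling genes were higher in cultured CAST/Ei cells (median 1.96, 11 of 17 at least 2-fold higher, 1 lower). Inhba, the activin A subunit (chromosome 13, 16011851 to 16031621), had 176.6 CPM (173.7 to 179.6) against 0.119 (0.0719 to 0.186). Inhbb stood at 5.73, the receptor Bmpr1a at 2.44 and Smad3 at 3.25. Extracellular matrix genes had a median of 1.99 (16 of 22 higher, 1 lower), with Timp1 at 5.90 and Col5a1 at 4.91. All 13 cell cycle genes were at least 2-fold higher (median 4.30), with Top2a at 276 CPM (272 to 279) against 0.132 (0.0817 to 0.202). Interferon and antigen presentation genes were lower (median -1.37, percentile 0.3, 7 of 11 lower, 2 higher). The interferon-induced Ifit1 had 1.19 against 30.1 CPM and the class I gene H2-K1 20.2 against 96.4, while B2m (1.32) and Ifitm3 (1.75) were higher. Nuclear oxidative phosphorylation genes were lower by less (median -0.49, percentile 1.72, 3 of 21 lower), with Ndufv1 at -1.56. Glial genes were higher in these cells (median 1.41, 9 of 15 higher, 2 lower), with Sox10 at 154.5 against 1.94 CPM. Glial injury genes had a median of 3.94 (8 of 9 higher) and Cd68 a ratio of 2.27, and fibroblast and vascular genes went both ways (median -0.18, 6 of 13 higher and 6 lower).

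By the naming rule, the CAST/Ei cultured cells were also higher in the TGF-beta target Pmepa1 (394 against 9.7 CPM), and the receptor tyrosine kinase Axl (275 against 3.74). So were the collagens Col1a2 and Col8a1 (4.51 and 5.61), Postn (7.48), the actin-binding Cald1 (4.06) and Gldn, which encodes the nodal adhesion protein gliomedin (7.06). They were lower in Dpp10 (29.6 against 855 CPM), Aldoc (-5.08), the potassium channel subunit Kcnip2 (-6.15) and the nociceptor phosphatase Acpp (-4.52). Lower as well were Paqr5 (-4.78), Cd55 (-3.69), Ctxn3 (-5.08), the neuropeptide Nmb (-3.64), Lgals9 (-3.45) and Tmem255a (-4.72). The regeneration-associated median was 2.35 over members of at least 50 CPM, and the subtype median was -1.65 with a pseudocount of 10 CPM. The median of all genes stood at 0.12 here, at 0.18 in the comparison of cultured strains and at 0.11 for the difference of responses, against 0.02, -0.03 and -0.03 with median-of-ratios scaling, and the matched lists carry the same shift.

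**Figure D3:**
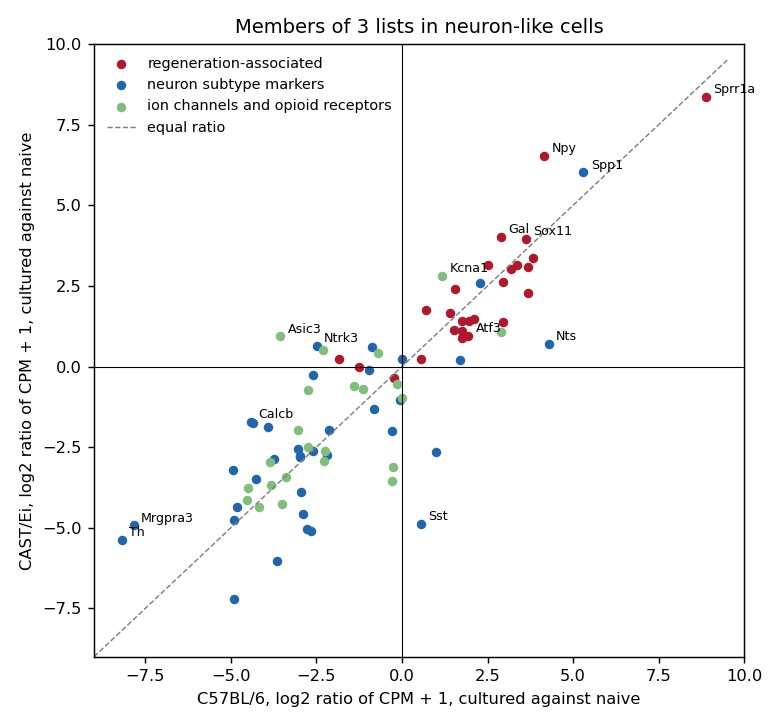
Each point is 1 gene of 3 lists, with its log2 ratio of CPM + 1, cultured against naive neuron-like cells, in C57BL/6 (horizontal axis) and CAST/Ei (vertical axis), and the dashed line marks equal ratios. Sprr1a lies at 8.89 and 8.36 and Th at -8.19 and -5.37, while Sst (0.55 and -4.87) lies on opposite sides of 0.

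Shares of neuron-like cells with at least 5 thinned reads showed how widely these markers were spread. Sprr1a was detected in 0.926% of naive and 82.1% (63.1 to 93.9) of cultured C57BL/6 cells, and in 0.69% and 81.2% (69.5 to 89.9) of CAST/Ei cells (unthinned 0.862, 83.3, 1.92 and 89.3%). In the other cultured cells the share was 27.9% in C57BL/6 but 87% in CAST/Ei, so the CAST/Ei share does not set neuron-like cells apart. The level does, with 461 and 774 CPM in CAST/Ei clusters 2 and 5 against 62.9 and 55.7 in clusters 4 and 6. Gal was detected in 50% (30.6 to 69.4) of cultured C57BL/6 and 98.4% of cultured CAST/Ei neuron-like cells against 32.4% and 100% of the other cells (unthinned 50 and 100%), while its level in CAST/Ei was 2543 and 5207 CPM in clusters 2 and 5 against 350.1 and 191 in clusters 4 and 6. Inhba was detected in 28.6% and 67.2% (54.3 to 78.4) of cultured neuron-like cells of the 2 strains and in 26.5% and 56.5% of the other cells (unthinned 41.7 and 84%). Its level was 95.1 and 24.3 CPM in C57BL/6 clusters 2 and 5 against 90.05 and 1.40 in clusters 4 and 6, so in C57BL/6 it does not set neuron-like cells apart from cluster 4, and 208 and 103.9 against 74.3 and 44.6 in CAST/Ei. Th was found in 30.6% of naive and 7.14% of cultured C57BL/6 cells and in 44.1% and 14.1% of CAST/Ei cells, with 0% in the other cultured cells of either strain (unthinned 36.2, 5.56, 60.9 and 16%). Mrgprd stood at 37% and 3.57% in C57BL/6 and at 42.8% and 15.6% in CAST/Ei (unthinned 43.1, 5.56, 61.5 and 16%). Tac1 stood at 83.3% and 32.1% in C57BL/6 and at 77.2% and 20.3% in CAST/Ei, near the 17.4% of other cultured CAST/Ei cells (unthinned 91.4, 30.6, 86.5 and 25.3%).

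Strain differences before culture were described by setting naive CAST/Ei neuron-like cells (clusters 1, 3, 8, 10 and 12) against naive C57BL/6 ones (clusters 1, 9, 11, 12 and 13). Most gene lists had medians near 0, while single genes lay far apart. Regeneration-associated genes had a median of 0.02 (1 of 24 at least 2-fold higher in CAST/Ei, 3 lower), with Anxa1 at 1.57 and the small heat shock protein Hspb1 at -2.09. Subtype markers had a median of 0.20 (5 of 36 higher, 5 lower), with Sst at 1.42 and the heavy neurofilament Nefh at -2.14. Ion channels had 0.23 (5 of 23 higher, 2 lower), with the irritant receptor Trpa1 at 328 against 67.8 CPM and Asic3 at 1.8 against 24. Prune2, among the most abundant transcripts of C57BL/6 cells (chromosome 19, 16956118 to 17223932), had 1141 CPM (1136 to 1147) in CAST/Ei against 14799.5 (14775 to 14824). The tetraspanin Tspan10 (chromosome 11, 120442644 to 120446950) had 46.1 CPM and no read in C57BL/6, at least 1454-fold higher, with a log2 ratio of CPM + 1 of 5.56. Fam213b (chromosome 4, 154895504 to 154899135) had no read in CAST/Ei and 41.6 CPM in C57BL/6, at least 2207-fold lower, with a log2 ratio of CPM + 1 of -5.41.

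Other genes higher in naive CAST/Ei were Serpina3h (5.49), the caveolar coat gene Ptrf (725 against 72.1 CPM), 5031414D18Rik (3.26), and the innate immune kinase Irak4 (3.27). The group also held the phospholipases Plcd3 and Pla2g4e (4.34 and 5.11), Gm15446 (4.66), Rsph1 (3.66), the sterol enzyme Lss (2.94), Gad1, the enzyme of GABA synthesis (90.6 against 0.592 CPM), and Mx2 (2.76). Lower in CAST/Ei were H2-T24 (-4.62), Ccdc6 (-3.93), Ppp1r16b (-4.43), Cdr2l (-3.73), Pcbd1 (-2.77), Golga7b (-3.54) and Zfp780b (-3.43). So were the growth factor homologue Fgf12 (189 against 1720.2 CPM), the chromatin protein Cbx3 (34.6 against 447) and the axonal adhesion protein Cntn1 (155.7 against 559). Nuclear oxidative phosphorylation genes were slightly lower in CAST/Ei (median -0.26, percentile 0.325, 0 of 21 by 2-fold or more), as were pan-neuronal genes (-0.16, percentile 1.97, 4 of 23 lower) and glial genes (-0.55, percentile 0.04, 5 of 13 lower, 1 higher), with S100b at 35.2 against 217 CPM. Not apart were activin and BMP signalling (0.22), extracellular matrix (0.06), cell cycle (0.20 over 2 genes), interferon and antigen presentation (-0.04), fibroblast and vascular (0.38) and glial injury genes (-0.31). In the lower range of title numbers the pan-neuronal median was 0.17 and the oxidative phosphorylation median 0.15, and without the cells highest in glial genes the glial median was 5.46e-05. CAST/Ei variants against the reference can lower the count of a gene, and this limit applies to each gene named here as lower in CAST/Ei. For a gene higher in CAST/Ei, such a loss of reads would make the difference too small.

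**Figure D4:**
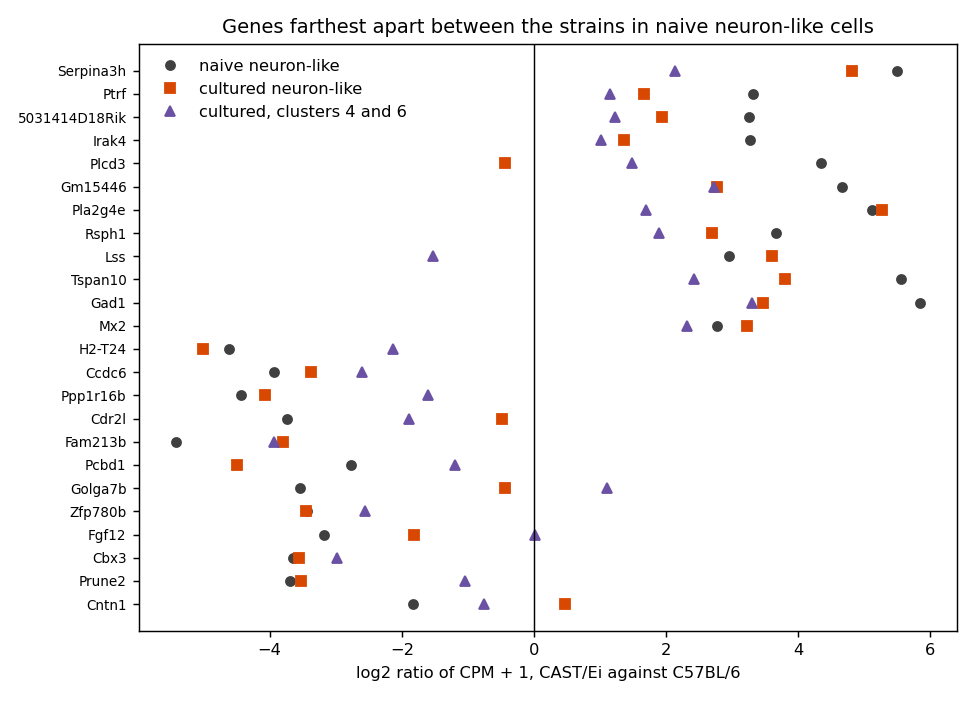
For the 24 genes named between naive strains (vertical axis), the log2 ratio of CPM + 1 of CAST/Ei against C57BL/6 (horizontal axis) is drawn in naive neuron-like cells, cultured neuron-like cells and cultured cells of clusters 4 and 6. In cultured neuron-like cells 20 of the 24 lay at least 2-fold apart in the same direction, and in clusters 4 and 6 also 20, with Plcd3, Cdr2l, Golga7b and Cntn1 the exceptions in the former and Lss, Golga7b, Fgf12 and Cntn1 in the latter.

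Cultured cells of the strains were compared to see whether the injured state differed, with 75 CAST/Ei and 36 C57BL/6 neuron-like cells of mainly clusters 2 and 5. Cells of the strains differed in complexity as well, with a median of 5916 genes in CAST/Ei against 8117.5 in C57BL/6 at equal thinned depth. Cluster 2, with 44 of the CAST/Ei and 12 of the C57BL/6 cells, had a median of 5339 genes and cluster 5 of 8968. Interferon and antigen presentation genes were lower in CAST/Ei, with a median of -1.69 below all matched lists (percentile 0), 7 of 10 at least 2-fold lower and 1 higher. Ifit3 had 6.23 CPM in CAST/Ei against 108.6, Ifit1 1.19 against 20.1, and the immunoproteasome subunit Psmb8 8.4 against 39.7. H2-K1 had 20.2 against 78.7, while the transcription factor Irf1 was higher (37.7 against 9.96). Over the pooled cells, regeneration-associated genes stood level as a list (median -0.09, 3 of 26 higher, 2 lower). Among them Gal (3240.2 against 1209 CPM, intervals 3228 to 3253 and 1194 to 1224), Npy (98.1 against 16.8) and Il6 (30.9 against 7.99) were higher in CAST/Ei and Atf3 lower (318 against 738). A part of the cells carries the C57BL/6 sum of Gal, whose median per cell was 115.6 and 5.48 CPM in clusters 2 and 5 against 1924 and 1843 in CAST/Ei. Subtype markers went both ways (median 0.59, percentile 94.9, 12 of 29 higher, 7 lower). Th (2.70), Calcb (2.55) and Trpv1, the capsaicin receptor (2.66), were higher and Sst (-4.01) and Nts (-2.90) were lower. Nuclear oxidative phosphorylation genes were lower (median -0.46, percentile 1.09, 3 of 21 lower), with Sdha at -1.51.

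The genes farthest apart by the naming rule in cultured cells were, on the CAST/Ei side, Gal, Hopx (321 against 7.69 CPM), the growth factor Fgf1 (349.6 against 25.7), the serotonin receptor Htr1d (4.15) and the sodium channel subunit Scn4b (91.1 against 1.33). The same side held Retsat (4.86), Sap18 (3.03), Zfp367 (1.58), Mir703 (3.35), Pisd-ps1 (1.25), and Gm14403 (3.99). The kinase Mylk4 (chromosome 13, 32700834 to 32783954) had 115.1 CPM against 1 read in C57BL/6, a ratio with a counting interval of 419 to 92188-fold. On the C57BL/6 side were the nuclease Dnase1l3 (14.1 against 585 CPM), Zfp317 (-3.82), Zfp780b (-3.45), H2-T24 (-5.01), Cbx3 (-3.56), and Prune2 (-3.53). They also included Rab31 (-2.81), Fam60a (-3.73), Churc1 (-2.76), Rpl21 (-3.61), Ppp1r16b (-4.08) and Ddx3y, on chromosome Y, with no read in CAST/Ei, at least 2542-fold lower. Mylk4 and Npy are leading genes of cluster 2, and Gal, Nts and Dnase1l3 of cluster 5, and the strains differ in the mix of these clusters. Inside cluster 2, Mylk4 had 149.5 CPM in CAST/Ei against 0 in C57BL/6, and Npy 119.5 against 30.9. Inside cluster 5, Gal had 5207 against 1810 and Dnase1l3 46.2 against 1190. These values argue against the mix as the whole cause for these genes, while no such value is given for Nts. Ion channels (0.09, 4 of 18 higher, 4 lower), pan-neuronal (0.11), activin and BMP (0.27, 6 of 17 higher, 2 lower, with Inhba at 1.57 and Acvr1 at -1.94), cell cycle (-0.07), matrix (-0.25), glial (0.14), fibroblast and vascular (0.65), glial injury genes (-0.20) and Cd68 (1.58) were not apart. The strain medians differed by cluster. In cluster 5, ion channels (0.64, percentile 99.27), activin and BMP (0.54, 99.08), cell cycle (-0.70, 0.02) and regeneration-associated genes (-0.20, 1.53) were apart. In cluster 2 the same lists were not (0.23, 0.33, 1.42 and 0.12). Subtype markers (1.99, percentile 99.91) and fibroblast and vascular genes (2.22, 99.48) were apart in cluster 2 but not in cluster 5 (0.32 and -0.22). Without the neuron-like cells highest in glial genes, which left 14 C57BL/6 and 41 CAST/Ei cells, the interferon median was -0.72 and the oxidative phosphorylation median 0.10.

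Whether the culture response itself differed in size between strains was described by the log2 ratio in CAST/Ei minus that in C57BL/6, which was not tested. Subtype markers as a list were not apart (median difference 0.18, percentile 73.3), but members went both ways, with 9 of 36 at least 2-fold higher and 10 lower. The median thus does not show that the markers responded alike, and its sign changed under some alternatives given below. Single markers differed, with Ntrk3 (3.13), Th (2.82) and Calcb (2.71) higher in the CAST/Ei response and Sst (-5.42) and Nts (-3.58) lower. Regeneration-associated genes had a median difference of -0.32 (percentile 2.33), while by 2-fold or more 5 of 26 were higher in the CAST/Ei response and 2 lower. The median kept its sign under 11 of 13 alternatives, with 0.03 the highest value. Gpr151 (-1.55), Anxa1 (-1.41) and Atf3 (-0.99) were lower and Npy (2.38), Il6 (2.06) and Gal (1.12) were higher. Interferon and antigen presentation genes were lower (-0.96, percentile 0.19, 6 of 12 lower, 1 higher), with Ifit3 at -2.69 and H2-K1 at -2.59. So were fibroblast and vascular genes (-1.12, percentile 0.075, 7 of 13 lower, 1 higher), with Rgs5 at -3.12. Activin and BMP genes had a difference of 0.52 (percentile 95.3, 3 of 17 higher, 2 lower), with Inhba at 1.78. Ion channels (0.25), pan-neuronal (0.20), cell cycle (0.05), oxidative phosphorylation (-0.19), matrix (-0.21), glial (0.14) and glial injury genes (0.48) were not apart.

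The single genes with the largest differences of response were Lhfpl1 (9.97), Mylk4 (6.74), the potassium channel Kcnk1 (5.10), Car8 (4.76) and the calcium sensor Vsnl1 (4.74) on the CAST/Ei side. Kcnk1 had 25.3 and 1.38 CPM in naive and cultured C57BL/6 and 8.36 and 28.1 in CAST/Ei. On the C57BL/6 side they were Ddx3y (-6.60), Thsd7b (-5.62), Zfp654 (-5.19, with 8.31 and 216 CPM in C57BL/6 and 20.6 and 12.8 in CAST/Ei), Ccdc141 (-4.90) and the deacylase Sirt5 (-4.88). With cultured cells of cluster 5 alone the Ccdc141 difference was 1.95. The regeneration-associated difference was 0.02 in the upper range of title numbers and 0.03 with cluster 2 alone, and the fibroblast and vascular difference was 0.30 over members of at least 50 CPM and 0.86 with cluster 2 alone.

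Sex-linked genes showed a structure that the group labels do not give. Ddx3y (chromosome Y, 1260771 to 1286629) had 94.5 CPM in cultured C57BL/6 neuron-like cells, no read in naive C57BL/6 or cultured CAST/Ei ones and 2 reads in naive CAST/Ei ones. Xist, transcribed from the inactive X chromosome, had 79.2, 136.6, 109.8 and 193 CPM in naive and cultured C57BL/6 and naive and cultured CAST/Ei. These are the 2 of 5 listed sex-linked genes in the table, and the medians of 3.68 for culture in C57BL/6, -3.04 between cultured strains and -3.28 for the difference of responses, apart from matched lists, are midpoints that describe neither gene. Between cultured strains Ddx3y stood at -6.58 and Xist at 0.50. The values for culture in CAST/Ei (0.81) and between naive strains (0.47), not apart, are those of Xist alone. Of the cultured C57BL/6 cells, 58 had at least 5 reads of Ddx3y, 42 of Xist, 0 of both and 11 of neither. In the order of their title numbers the cells with either formed 4 blocks, Ddx3y in numbers 1 to 28 and 53 to 89 and Xist in 29 to 52 and from 90 on. There were 3 switches among 99 neighbouring pairs against 48.7 for a random order. The 4 blocks held 40.7, 33.3, 31.4 and 24% neuron-like cells. Neuron-like cells were 19 of the 58 cells with Ddx3y (32.8%, 21 to 46.3) and 10 of the 42 with Xist (23.8%, 12.1 to 39.5).

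**Figure D5:**
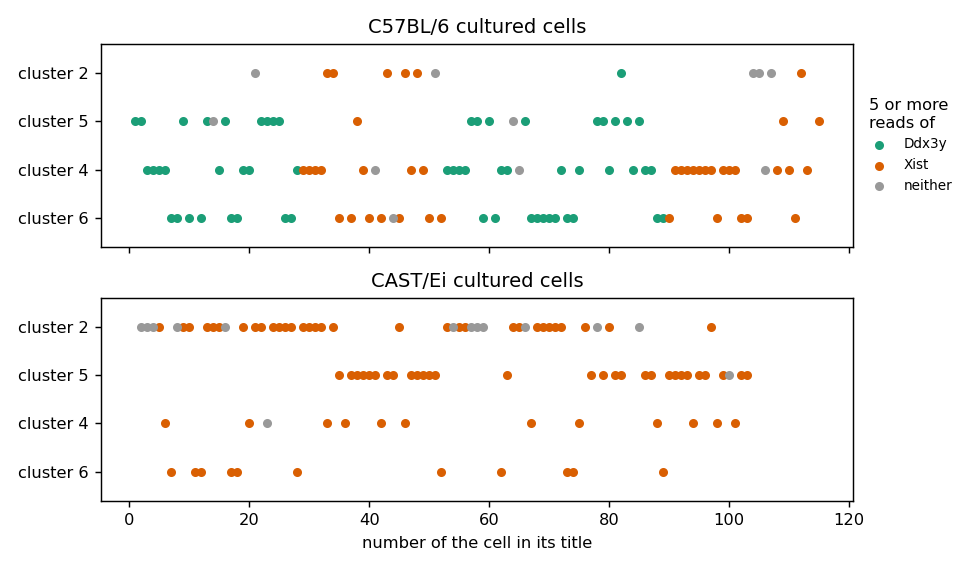
Each point is a cultured C57BL/6 (top) or CAST/Ei (bottom) cell, placed by the number in its title (horizontal axis) and its cluster (vertical axis) and coloured by at least 5 reads of Ddx3y, of Xist or of neither, without the 2 cells of clusters 3 and 11. Cells with Ddx3y occur in C57BL/6 alone, in numbers 1 to 28 and 53 to 89.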

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

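The interferon pattern was picked after the list medians were seen, and its tests of glial RNA, of CAST/Ei variants and of the mix of clusters were chosen only after the result was seen.

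Some gene lists had medians of opposite sign in the 2 strains or the 2 states, at least 1 of the 2 apart from matched lists, and these differences were not tested. Interferon and antigen presentation genes stood at 0.27 for culture in C57BL/6 and -1.37 in CAST/Ei, and fibroblast and vascular genes at 1.28 and -0.18. Between strains, pan-neuronal genes stood at -0.16 in naive and 0.11 in cultured cells, glial genes at -0.55 and 0.14, and sex-linked genes at 0.47 and -3.04. The sex-linked values rest on Xist alone in naive cells and on Xist and Ddx3y in cultured cells, and Xist itself kept its sign (0.47 and 0.50).

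Interferon and antigen presentation genes had a median log2 ratio of -1.69 between cultured CAST/Ei and C57BL/6 neuron-like cells. The values argue against the sex of the C57BL/6 animals (-1.89 against C57BL/6 cells without Ddx3y reads), the mix of clusters 2 and 5 (-2.01 inside cluster 2 and -1.37 inside cluster 5) and CAST/Ei variants that lose reads (-0.041 in naive neuron-like cells, where the same genes would be short of reads) as the whole cause. RNA of glia may account for part of it, since the median was -0.72 without the cells highest in glial genes, although only 14 C57BL/6 cells were left and 13 of the 15 measured glial genes reach 5 CPM in naive neuron-like cells of at least 1 strain. Separate cultures or animals of the 2 strains cannot be told apart from strain, because no label names them. Against the lower C57BL/6 title range the median was -1.30 with the lower CAST/Ei range and -1.02 with the upper, the closest to 0 of the 4 pairs. Against the upper C57BL/6 range it was -2.38 and -1.998, so the value also varied within the C57BL/6 group. A strain difference in interferon state stays open as untested, and with few cells the median was also -1.44 in cultured cells of cluster 4 (13 CAST/Ei and 43 C57BL/6 cells) and -1.85 in cluster 6 (11 and 32 cells), while in naive cells it was -0.34 in cluster 1, 0.42 in cluster 12 and -0.98 in cluster 7.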

How the results depend on the processing

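Alternatives with C57BL/6 cultured cells without Ddx3y reads, or with cluster 2 or cluster 5 alone, were chosen after seeing the data. No paired analysis was possible because the numbers in the titles, although shared between groups, only name cells, and no result comes from a test. Of 34 list medians apart from matched lists, 27 kept their sign under each of the 13 alternatives run on lists. Among these the regeneration-associated medians for culture ranged from 1.83 to 2.55 in C57BL/6 and from 1.54 to 2.35 in CAST/Ei, and the interferon median between cultured strains from -2.01 to -0.72. Ratios and list medians below changed sign or shifted by 1.5-fold or more, shares left the interval of the reported value, and the cause was not tested. The share of neuron-like cells, CAST/Ei naive, percent, was 94.3 in the upper title range, and that of cultured CAST/Ei cells 61.6% (Ward) and 62.6% (cell by cell). With a pseudocount of 10 CPM, subtype medians were -1.50 for culture in C57BL/6, -1.65 in CAST/Ei and -0.041 for the difference. Over members of at least 50 CPM the regeneration-associated median for culture in CAST/Ei was 2.35 and the fibroblast and vascular difference 0.30. Without the cells highest in glial genes, the subtype difference was -0.12, and between strains oxidative phosphorylation stood at 0.10 and interferon at -0.72 in cultured cells, and glia at 5.46e-05 in naive cells. In the lower title range the subtype difference was -0.47, and between naive strains pan-neuronal genes stood at 0.17 and oxidative phosphorylation at 0.15, while in the upper range the regeneration-associated difference was 0.018. With cluster 2 alone, subtype markers stood at -3.84 and fibroblast and vascular genes at -0.65 for culture in C57BL/6, and the differences were -0.039 for subtype, 0.034 for regeneration-associated and 0.86 for fibroblast and vascular genes. With cluster 5 alone the list median, neuron subtype markers, culture in CAST/Ei, was -1.81 and the Ccdc141 difference 1.95. Among ratios of named genes, 39 stayed and 67 moved so with a pseudocount of 10, 92 and 14 with Ward clusters, 89 and 17 with the mean of CPM per cell, 67 and 39 without the cells highest in glial genes, 62 and 44 in the lower and 63 and 43 in the upper title range, 79 and 27 without Ddx3y cells, 60 and 46 with cluster 2 alone, and 66 and 39 with cluster 5 alone, where Ccdc141 changed sign, while median-of-ratios scaling and the stricter cell filter moved 0. Of up to 84 list medians, 50 stayed, 31 moved and 2 reversed without the cells highest in glial genes, 56, 26 and 2 in the lower and 62, 20 and 1 in the upper title range, 59, 21 and 3 with cluster 2 alone, and 64, 14 and 1 over members of at least 50 CPM. None reversed with the rest, where 63 stayed with cluster 5 alone, 66 with a pseudocount of 10, 68 without Ddx3y cells, 70 with the mean of CPM per cell, 71 with Ward clusters, 76 with median-of-ratios scaling, 80 with no low filter and 84 with the stricter cell filter. Of the shares of cells with a marker, 65 stayed and the larger part moved with 1 thinned read as the limit, and 56 moved without thinning. The macrophage list gave no value for culture in C57BL/6 with cluster 2 alone, in the upper title range or without the cells highest in glial genes, and over members of at least 50 CPM neither it nor the cell cycle list between naive strains gave one. Depth limits the shares of cells, and 50 cells lay under the thinning depth.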

Other observations

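Tests of whether strain genes keep their direction in other cells were chosen only after the result was seen, and the cell cycle and strain patterns were picked after the list medians were seen.

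Heat shock and immediate early genes as lists were not higher in cultured cells, unlike regeneration-associated genes. Heat shock genes had a median log2 ratio of -1.37 for culture in CAST/Ei (percentile 0.05, 0 of 10 at least 2-fold higher, 6 lower) and -0.17 in C57BL/6 (percentile 28.25, 0 higher, 4 lower). The constitutive chaperone Hspa8 was lower in both strains (948 against 2178 CPM in C57BL/6 and 493 against 1656 in CAST/Ei), as was Hsph1 (-1.70 and -1.20). Its co-chaperones Dnaja1 (-0.28 and -1.77) and Dnajb1 (0.23 and -1.54) were lower by 2-fold or more in CAST/Ei alone, and the endoplasmic reticulum chaperone Hspa5 (0.66 and 0.21) in neither. Between strains the heat shock medians were 0.37 in naive and -0.33 in cultured cells, and the difference of responses was -0.50, none of them apart. Immediate early genes were not apart in any comparison, with medians of 0.29 and -0.01 for culture in C57BL/6 and CAST/Ei, -0.02 and -0.46 between naive and cultured strains and -0.30 for the difference. Single members were far apart in C57BL/6, with Dusp1 at 470 cultured against 63.9 CPM naive, Fos at 1170.2 against 437 and Btg2 at 54.4 against 237.

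Cholesterol synthesis genes were lower after culture in C57BL/6 (median -0.85, percentile 1.22, 0 of 15 at least 2-fold higher, 5 lower), with Dhcr7 at -1.80, Mvd at -1.55, Fdft1 at -1.46, Fdps at -1.41 and Cyp51 at -1.18. In CAST/Ei the median was -0.48 (percentile 4.53, 1 higher, 1 lower), and it was 0.11 between naive strains, 0.27 between cultured strains and 0.40 for the difference of responses, none of them apart. Lss (2.94 naive and 3.595 cultured), Dhcr7 (1.44 and 3.23) and Hmgcs1 (1.32 and 1.45) were higher in CAST/Ei in both states, and the feedback regulator Insig1 (-1.63 and -1.15) was lower. Glia make cholesterol as well, and reads of these genes were not assigned to a cell type.

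Cell cycle genes in cultured neuron-like cells, with medians of 4.22 in C57BL/6 and 4.30 in CAST/Ei, are unexpected in cells that no longer divide and were given ara-C. Glia caught together with a neuron are argued against as the whole cause, since in the cultured cells lowest in glial genes the cell cycle median against naive cells was 3.72 in C57BL/6 (9 cells, glial median -1.11) and 4.65 in CAST/Ei (19 cells, -0.60), with Top2a detected in 55.6% and 78.9% of them. RNA of the other cultured cells cannot be told apart, because the excess of glial genes as a percent of those cells' level was 2.33 times that of cell cycle genes in C57BL/6 and 3.89 times in CAST/Ei, and the 12 or 13 cell cycle members spread from 8.46 to 63.3% and from 8.43 to 55.5%, the glial ones from 62.1 to 91.05% and from 23.1 to 166.3%. Glial members above 100% in CAST/Ei exceed the level pooled over clusters 4 and 6. Sox10 had 154.5 CPM in CAST/Ei neuron-like cells and 91.8 in the pooled cells, but 154.8 in cluster 6 and 23.9 in cluster 4. The percents thus depend on the pooling and are no plain measure of RNA taken up from those cells. Cell cycle expression in injured neurons themselves may contribute and was not tested.

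Most genes far apart between naive strains kept their direction elsewhere. By 2-fold or more and the same way, 20 of 24 differed in cultured neuron-like cells and 20 of 24 in cultured cells of clusters 4 and 6. This fits a strain variant acting in mapping or in cis, but any other strain difference shared by these cells would give it too. Loss of CAST/Ei reads in mapping could bear only on the genes lower in CAST/Ei. In clusters 4 and 6 Lss (-1.52 against 2.94 naive) and Golga7b (1.11 against -3.54) went the other way, which goes against such a variant for these 2. Serpina3h, 5031414D18Rik, Pla2g4e and Tspan10 counted with under 5 CPM in both strains. Reads shared with paralogs or pseudogenes are argued against as the general cause for these genes, since 16.7% of the 24 had 10% or more of their words in another gene against 19.1% of all genes. Of the 24 genes named between cultured strains 9 did (37.5%), so for those this cause stays open. A variant that changes mapping and one that changes expression were not separated, and a strain difference in expression stays open as untested.

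Cultured cells of clusters 2 and 5 followed the order of title numbers in CAST/Ei, with 15 switches of cluster among 73 neighbouring pairs against 35.7 for a random order, and 12 among 34 against 15.8 in C57BL/6. In C57BL/6, blocks with Ddx3y held 10 and 10 cells of cluster 5 and 1 and 1 of cluster 2, and blocks with Xist 1 and 2 of cluster 5 and 6 and 4 of cluster 2. Cultured C57BL/6 cells with at least 5 reads of Ddx3y numbered 58, of Xist 42 and of both 0, so this group holds cells of more than 1 animal, which the labels do not tell apart.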
